A study of Mus musculus with 6 samples.

How the data were processed

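PolyA RNA was measured in J1 mouse embryonic stem cells, a widely used line, in 3 wild-type (WT) libraries and 3 libraries of cells with both copies of Mettl5 disrupted (Mettl5 knockout). Per the labels, the cells were grown for 7 days in medium with serum and LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated. RNA was selected on oligo dT beads in 2 rounds, fragmented to 100 nt, and 0.1 µg was used for stranded libraries that were sequenced on an Illumina instrument. Genotype and replicate number were taken from the sample titles. The labels do not say that replicates were separate cultures or clones, so the p-values measure the spread between these samples, which may be technical.

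Per the submitters' processing notes, kallisto, sleuth and the mm10 build were used; versions, transcript annotation and strand setting are not given in the sources used here. The deposited table held 24191 Ensembl genes in 6 libraries, with 2 signal columns per gene, scaled reads and a TPM column, as named per the file headers. The scaled reads deposited by the authors were not whole numbers. Each library had a step of its own, and 29.9% to 32.7% of values from 0.5 to 40 lay within 0.02 of its whole multiples. The median share over all steps tried in the same library was 3.33% to 3.53%. Estimated counts divided by a size factor would give such steps. The deposited TPM signal had been rescaled too, since it summed to 969840 to 978170 in WT and 1019930 to 1022470 in knockout libraries, and is called the TPM scale here. Depth estimated from the steps was 52740000, 47620000 and 38550000 fragments in WT replicates 1, 2 and 3 and 40440000, 59660000 and 58830000 in knockout replicates 1, 2 and 3. The scaled reads summed to 46077000 to 46541000 in WT and 51500000 to 51830000 in knockout libraries.

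Before the data were examined, a count test on gene counts was planned, with limma for any normalized unit. Because the deposited values were not counts, limma (3.58.1, R 4.3.3) with an intensity trend was applied to log2(scaled reads + 1) of the 24183 genes with a mean of at least 1 scaled read, and p-values were adjusted by Benjamini-Hochberg. The threshold was an adjusted p of 0.05. Fold changes are on the log2(scaled reads + 1) scale, knockout against WT, with their standard error (SE), and understate the change of low genes. Levels are means ± SD of the TPM scale. The 2 columns are scaled differently, so a small fold change can differ, even in sign, from the levels printed beside it. Mean Nanog, for one, went from 158 to 157 on the TPM scale but from 16858 to 17328 scaled reads. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9. The test was tried on simulated values for 24060 genes of this comparison, with 200 genes changed. It recovered 56%, 68%, 84% and 94% of genes changed by 1.5, 2, 4 and 8 fold, and 73.7%, 94.1%, 100% and 100% of those over 20 scaled reads. Of 156 simulated calls, 5 were unchanged genes (3.2%). The simulation gave all genes the same spread, and far more genes were called in the real comparison, so these shares need not hold there.

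Gene names, coordinates and biotypes came from GENCODE M21 on GRCm38, the assembly also called mm10. It held 23846 of the listed identifiers, and 345 had no match. The values of 672 genes were identical to those of another gene, as happens when reads are split between identical copies. Members of multigene families, genes with processed pseudogenes, genes inside other genes and antisense genes are uncertain for that reason.

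The genes named in the report were chosen by a rule fixed before the data were examined. It takes Mettl5, then Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Trmt112, Fbxw7 and Myc. It adds the 8 largest fold changes in each direction among genes past the threshold with at least 5 on the TPM scale in the higher group and no overlap between groups, leaving out unnamed, Gm-number, Rik and pseudogene symbols. It also takes up to 3 members with the smallest p-values of each of 30 gene lists fixed at the same time. Some genes that this rule takes are not reported here. Lists were tested against the other genes with camera at a preset correlation of 0.01 and with camera at an estimated correlation. They were also tested with fry, which asks whether a list changed without reference to the other genes. Each test was adjusted over the 30 lists. Chromosomes were tested with camera in the same way.

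Alternatives were other rescalings of the libraries, filters, pseudocounts, the TPM column, voom weights, a test against a 1.5-fold change, a replicate block, log2 values centred per chromosome, and leaving out each library in turn. Principal components used the 500 most variable genes on log2 counts-per-million of the scaled reads. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.48 to 9.02, and all 6 libraries were kept.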

Results

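The series measured polyA RNA in J1 mouse embryonic stem cells with and without Mettl5, the methyltransferase that places N6-methyladenosine on 18S ribosomal RNA, with 3 libraries per genotype. It asked how loss of the enzyme bears on pluripotency and developmental programmes. Estimated depth was 38550000 to 59660000 fragments per library, and the median coefficient of variation between replicates was 4.15% in WT and 3.56% in knockout libraries. The first principal component held 97.2% of the variance and separated the genotypes. Pearson correlations across genes were 0.997 to 0.999 within a genotype and 0.967 to 0.969 between genotypes.

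Mettl5 (ENSMUSG00000051730, mm10 chromosome 2, 69871198 to 69885615) was at 50.3, 48.6 and 48.7 on the TPM scale in the WT libraries and at 3.65, 3.58 and 3.32 in the knockout libraries. Its log2 fold change was -3.73 (SE 0.0522, limma adjusted p 5.4e-11). Which part of the gene was altered is not given in the sources used here. Trmt112, the activating partner of METTL5, was at 77.1 ± 3.35 in WT and 74.7 ± 2.12 in knockout cells (SD, n = 3), a log2 fold change of 0.02 that did not pass the threshold (limma adjusted p 0.635) and passed it in the other direction when libraries were rescaled to equal totals (-0.13).

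Knockout cells had less naive pluripotency RNA, a small fall in Pou5f1 RNA, no called change in Nanog RNA, and more RNA of most primitive streak genes and of contractile and keratin genes. Zfp42 (also called Rex1), a marker of naive cells, fell from 584 ± 4.32 to 238 ± 2.59 on the TPM scale, while the keratins Krt8 and Krt18 rose from 29.4 ± 0.495 and 20.9 ± 0.502 to 782 ± 10.9 and 737 ± 19.1 (SD, n = 3). The smooth muscle genes Tagln and Acta2 rose from 16.7 ± 0.871 and 3.10 ± 0.215 to 732 ± 4.97 and 234 ± 4.96. T, the primitive streak factor brachyury, rose from 1.18 ± 0.21 to 63.4 ± 3.86. The plot of expression per library shows these genes.

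**Figure D1:**
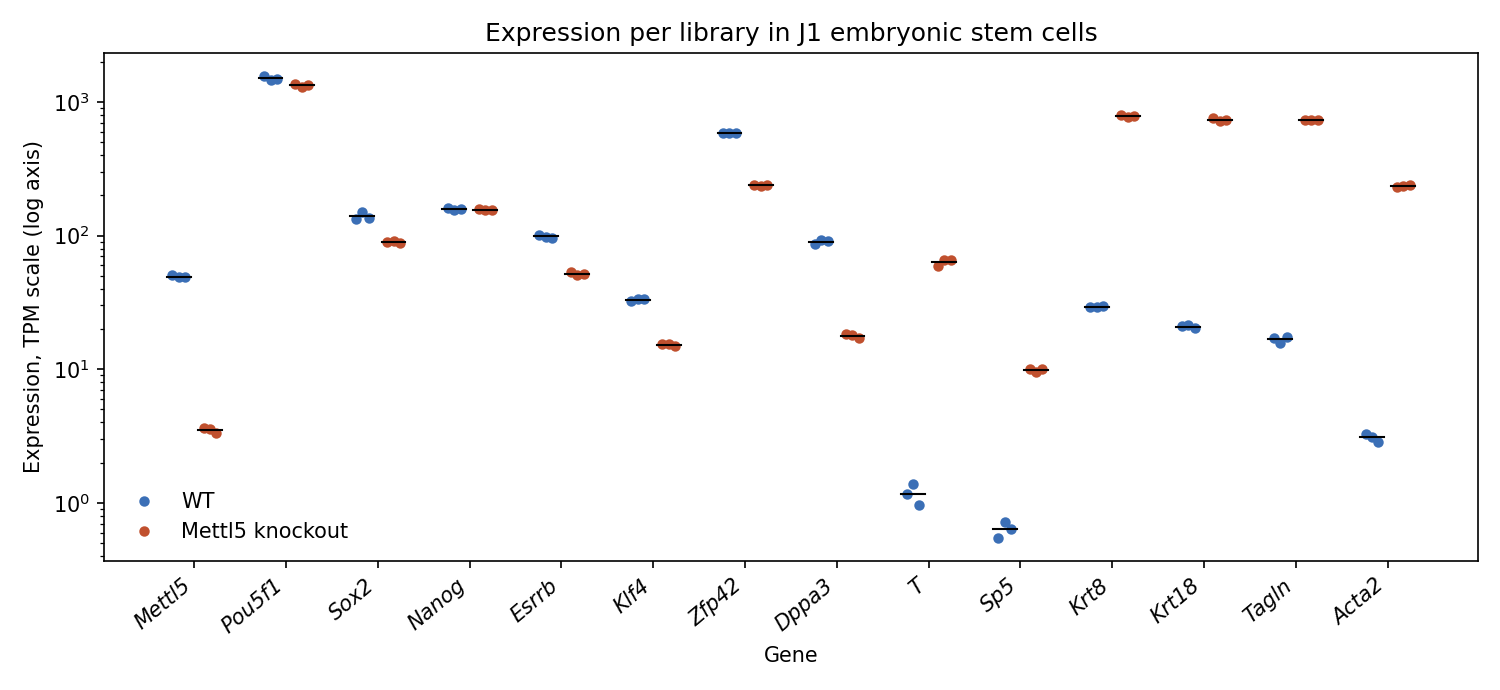
Expression of 14 genes on the TPM scale (log axis) in each WT library (blue) and each Mettl5 knockout library (red), with black lines at the means of 3 libraries. Mettl5, Zfp42 and Dppa3 were lower in every knockout library than in every WT library, and T, Sp5, Krt8, Krt18, Tagln and Acta2 were higher, while Nanog was at 158 in WT and 157 in knockout cells.

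Of 24183 tested genes, 8137 were higher and 6998 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05), and 2757 and 2402 of these changed by at least 1 on the log2 scale. The split depends on the scaling. With libraries rescaled to equal totals, which moves the median of all genes from 0.00 to -0.15, 6309 genes were higher and 9147 lower, so the share of higher genes among those called went from 53.8% to 40.8%. All 6998 lower genes were called lower with equal totals too, so only calls of higher genes were lost or turned. Genes on chromosomes 6, 8 and 11 made up 17.3% of tested genes and 31.9% of the lower ones.

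The largest rises that the naming rule takes were those of Csf1, Acta2, Prss23, Thbs1, Acta1, Sprr2a3, T and Edn1. Csf1, a macrophage growth factor, had a log2 fold change of 6.41 (SE 0.0705), from 0.277 ± 0.0167 to 23.4 ± 0.979 on the TPM scale, and the serine protease gene Prss23 one of 6.07 (SE 0.129), from 1.80 ± 0.353 to 115 ± 2.01 (SD, n = 3). Thbs1, encoding the matrix protein thrombospondin 1, rose by 6.0, the skeletal muscle actin gene Acta1 by 5.99, the cornified envelope gene Sprr2a3 by 5.95 and Edn1, the precursor of endothelin 1, by 5.73. The largest falls were in the X-linked lymphocyte-regulated genes Xlr5a (-5.89), Xlr4a (-5.62), Xlr4b (-5.54), Xlr3a (-5.26) and Xlr5b (-4.83), in the small nucleolar RNAs Snora81 and Snora9, and in Fyb. Xlr3a fell from 65.7 ± 2.16 to 1.59 ± 0.0704 on the TPM scale. Xlr genes are near-identical copies that share reads, so their individual values are uncertain. Snora81 was listed at 0 in all 3 knockout libraries and at 13.99, 29.5 and 38.3 in the WT libraries. Fyb, an adaptor of T cells, was uneven in WT, at 1.33, 3.54 and 11.7, against 0.0846, 0.0434 and 0.131 in the knockout. Every adjusted p in this group was 0.000176 (Fyb, limma) or smaller.

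Naive pluripotency genes fell as a group: of 23 tested, 18 were lower, 1 was higher and 4 did not pass (median log2 fold change -0.60, camera adjusted p 4.12e-07, and 0.0386 with an estimated correlation). Dppa3, a maternal factor of early embryos, had a log2 fold change of -2.27 (SE 0.0431) and fell from 90.2 ± 3.22 to 17.8 ± 0.66 on the TPM scale. Zfp42 fell by 1.24, Socs3, a target of LIF signalling, by 1.40, and the transcription factor genes Klf4 and Esrrb fell by 1.05 and 0.88 (limma adjusted p 2.51e-08 and 1.67e-08). Zfp42 is on chromosome 8, Dppa3 on 6 and Socs3 on 11, where genes were lower in general. With log2 values centred per chromosome, 18 members were lower and 2 higher.

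Core pluripotency genes went both ways, with 8 of 19 higher, 8 lower and 3 not called (9 higher and 8 lower adjusted over the list alone). The median was 0.04, the mean 0.005 and camera's direction down (adjusted p 0.964), and with equal totals the median was -0.12, with 6 higher and 11 lower. Pou5f1, which encodes OCT4, was at 1498 ± 54.2 in WT and 1330 ± 41.7 in knockout cells (SD, n = 3; log2 fold change -0.09, limma adjusted p 0.0343). Its call was lost when WT replicate 1 or 3 or knockout replicate 2 or 3 was left out (adjusted p 0.0706 to 0.125). Sox2 fell by 0.58 on the log2 scale and Tdgf1, a NODAL co-receptor, by 0.46. Lin28a, an RNA-binding regulator of let-7, and Sall4 rose by 0.61 and 0.47. Nanog, at 158 ± 2.18 and 157 ± 0.818 on the TPM scale, had a log2 fold change of 0.04 (limma adjusted p 0.158) that became -0.12 with equal totals and 0.33 with chromosome centring, both past the threshold.

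Genes of the formative or primed state were mostly higher: 14 of 20 rose and 5 fell (median 0.67, camera adjusted p 0.0193, and adjusted p = 0.121 with an estimated correlation). Cldn6, a tight junction gene, rose by 2.01 and the WNT receptor gene Fzd2 by 1.77, whereas Etv4, an FGF-responsive factor, had a log2 fold change of -1.30. Among primitive streak and mesendoderm genes, 14 of 19 were higher and 1 lower (1 more lower adjusted over the list alone), with a median of 2.11 (camera adjusted p 3e-05, and 0.0386 with an estimated correlation). T rose by 5.80, the WNT target Sp5 by 4.0 and Nodal by 1.06. Mesoderm genes had 17 of 21 higher and 3 lower (median 2.15, camera adjusted p 4.93e-05, and 0.0386 with an estimated correlation), with the smallest p-values in Acta2 (6.29), Tagln (5.52) and the homeobox gene Msx2 (4.23). The 3 lower members, named after their values were seen, were Meox1 (-2.41), Tbx6 (-0.69) and Des (-0.63). Several higher members were at low levels, such as Hand2 at 0.142 ± 0.0337 and Foxf1 at 0.314 ± 0.015 on the TPM scale in knockout cells (SD, n = 3).

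Trophectoderm genes had 13 of 18 higher and 3 lower (median 1.43, camera adjusted p 0.000963, and adjusted p = 0.068 with an estimated correlation). Its members with the smallest p-values were Krt8, Krt18 and Id2, which rose by 4.79, 5.20 and 3.25. Krt8 and Krt18 are also expressed in many other epithelia. The trophectoderm factor genes Cdx2 and Gata3, named after their values were seen, rose by 4.39 and 3.70. Their levels stayed low, at 5.38 ± 0.144 and 1.91 ± 0.25 on the TPM scale in knockout cells (SD, n = 3). Other members did not follow: Rhox6 (-1.1), Rhox9 (-0.69) and Ascl2 (-0.41) fell, and Elf5 and Tead4 did not pass the threshold. Hox genes had 27 of 32 higher and none lower (median 1.63, camera adjusted p 3.17e-05, and 0.0386 with an estimated correlation), at low levels. Hoxb9 rose from 0.215 ± 0.0183 to 2.29 ± 0.0777 on the TPM scale and Hoxd9 from 0.105 ± 0.0147 to 1.70 ± 0.0449 (SD, n = 3). Neuroectoderm genes had 10 of 26 higher and 6 lower (median 0.27, camera adjusted p 0.42). Cdh2, Nes and Nefl rose by 3.27, 2.51 and 2.21.

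Endoderm genes did not move together. Of 21, 9 were higher and 11 lower (median -1.02, camera adjusted p 0.145). Cubn, an endocytic receptor of visceral endoderm, fell by 3.76 and the laminin gene Lama1 by 2.23, while Sparc, a matrix protein gene, rose from 161 ± 1.39 to 317 ± 3.87 on the TPM scale. Germline genes controlled by DNA methylation had 18 of 23 lower and 3 higher (median -0.74, camera adjusted p 4.93e-05, and adjusted p = 0.0822 with an estimated correlation). The meiotic genes Smc1b, Stra8 and Tex11 fell by 2.89, 2.06 and 1.94. Genes of the 2-cell-like state, a rare state of stem cells resembling early cleavage embryos, had 18 of 19 higher and none lower (median 2.05, camera adjusted p 3.88e-07, and 0.0386 with an estimated correlation). Zscan4f rose from 14.7 ± 0.726 to 67.1 ± 1.75 on the TPM scale, and Zscan4e and Zscan4a had log2 fold changes of 2.37 and 2.58. The Zscan4 genes share reads, so the split between them is uncertain.

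**Figure D2:**
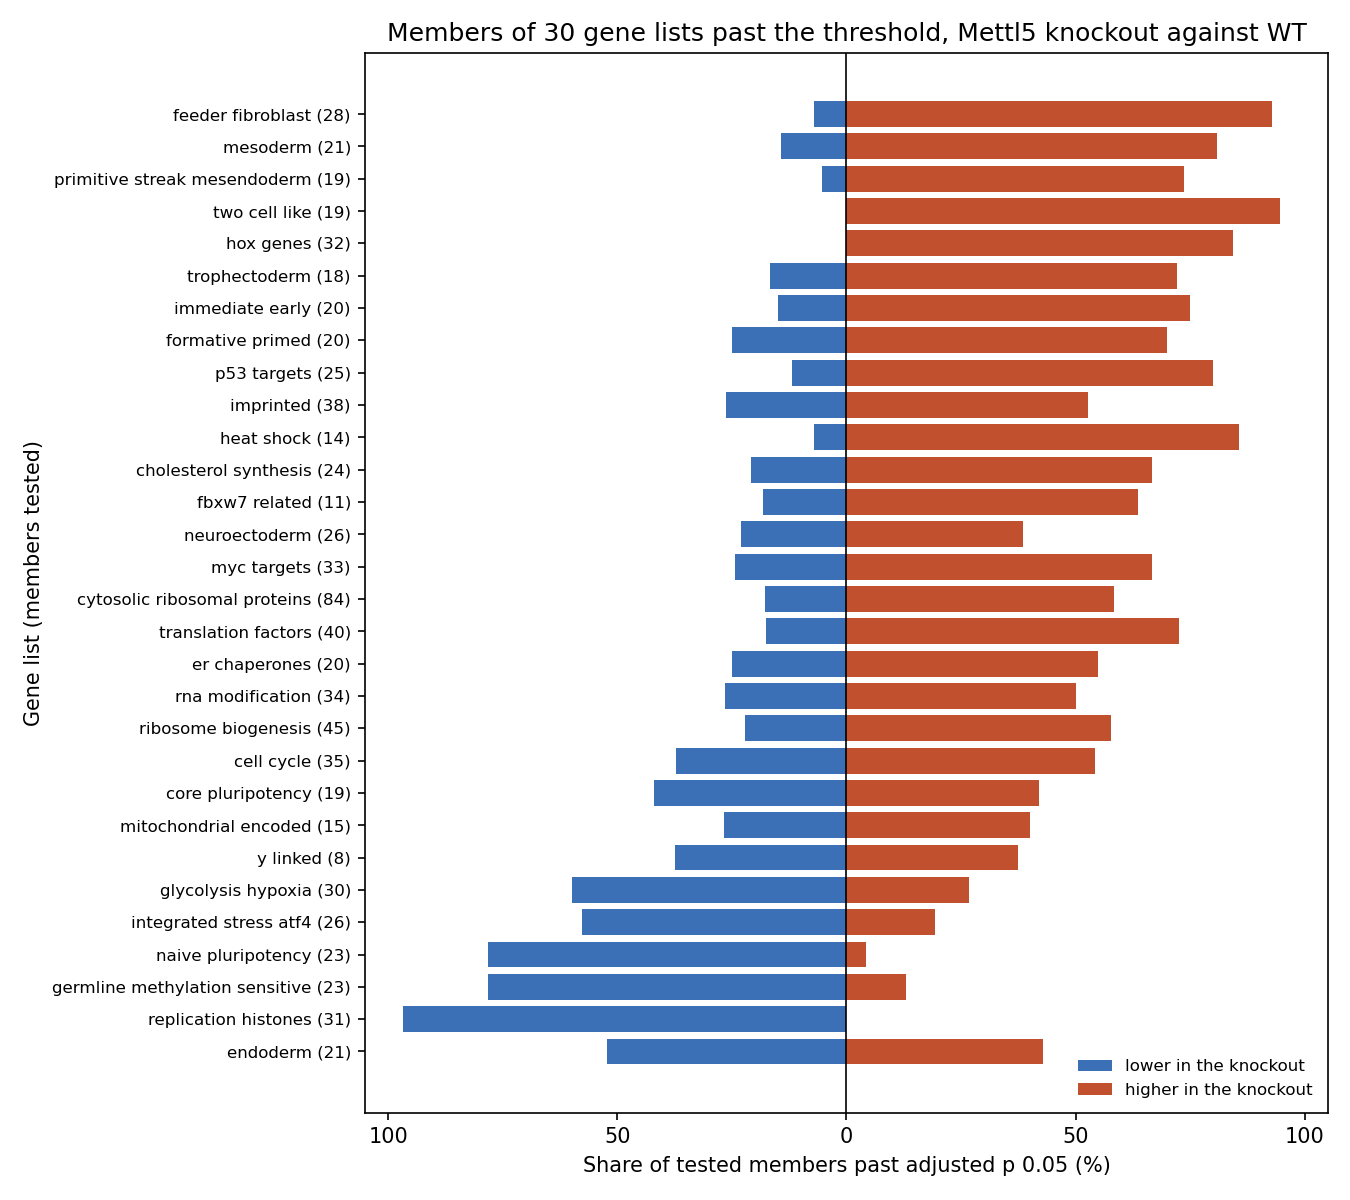
Share of tested members of each of 30 gene lists that were higher (red, to the right) or lower (blue, to the left) in Mettl5 knockout than in WT cells at a limma adjusted p under 0.05, sorted by the median log2 fold change, with the number tested in parentheses. The feeder fibroblast list (26 of 28 higher) and the replication histone list (30 of 31 lower) lie near the ends. With equal totals the medians of the core pluripotency, ribosome biogenesis, RNA modification, cell cycle and mitochondrial lists change sign.

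Cytosolic ribosomal protein genes had small changes, with 49 of 84 higher and 15 lower (50 and 16 adjusted over the list alone; median 0.22, camera adjusted p 0.00185, and adjusted p = 0.328 with an estimated correlation). Rpl7, Rpl6 and Rpsa rose by 0.66, 0.55 and 0.54. With equal totals 37 were higher and 29 lower, with a median of 0.06 and a camera adjusted p of 0.122. Ribosome biogenesis genes had 26 of 45 higher and 10 lower (median 0.12, camera adjusted p 0.086), which became 10 higher and 18 lower with equal totals. With log2 values centred per chromosome, 27 were higher and 4 lower (camera adjusted p 0.00413). Wdr12 and Gnl3 rose by 0.55 and 0.45, and Pes1, on chromosome 11, had a log2 fold change of -0.40 that became 0.02 when values were centred per chromosome. Translation factors had 29 of 40 higher and 7 lower (30 and 7 adjusted over the list alone; median 0.19, camera adjusted p 0.00193, and adjusted p = 0.0822 with an estimated correlation). The elongation factor genes Eef1a1, Eef1b2 and Eef1g rose by 0.75, 0.51 and 0.42. With equal totals 17 were higher and 12 lower (camera adjusted p 0.199).

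RNA modification genes had 17 of 34 higher and 9 lower (median 0.13, mean -0.005, camera direction up with adjusted p 0.276), and 12 and 13 with equal totals. Apart from Mettl5, the m6A methyltransferase gene Mettl16 and the demethylase gene Alkbh5 had log2 fold changes of -0.64 and -0.63. Both are on chromosome 11. Fbxw7, a ubiquitin ligase subunit that degrades MYC and JUN, rose from 7.20 ± 0.0587 to 11.9 ± 0.417 on the TPM scale (log2 fold change 0.77, limma adjusted p 9.28e-08), and Myc rose by 0.34. In the list of Fbxw7 and its substrates and partners, 7 of 11 were higher and 2 lower (median 0.28, camera adjusted p 0.155). Jun rose by 2.57 and Usp28, a deubiquitinase acting against FBXW7, had a log2 fold change of -1.13. MYC target genes had 22 of 33 higher and 8 lower (23 and 8 adjusted over the list alone; median 0.24, camera adjusted p 0.0166, and adjusted p = 0.201 with an estimated correlation). With equal totals 15 were higher and 9 lower, with a median of 0.08 and a camera adjusted p of 0.219. Cdk4 and Odc1 rose by 0.91 and 0.53, and Hk2 had a log2 fold change of -0.79.

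Targets of p53 had 20 of 25 higher and 3 lower (median 0.65, camera adjusted p 2.5e-06, and 0.0386 with an estimated correlation). Perp rose from 11.5 ± 0.272 to 114 ± 0.63 on the TPM scale, Plk2 from 9.75 ± 0.421 to 84.7 ± 0.805 and Pmaip1 (NOXA) from 6.64 ± 0.163 to 21.5 ± 0.269 (SD, n = 3). Immediate early genes had 15 of 20 higher and 3 lower (median 1.07, camera adjusted p 0.000199, and 0.0455 with an estimated correlation), among them Jun, Klf6 (2.08) and Dusp1 (1.74). Heat shock genes had 12 of 14 higher and 1 lower (2 lower adjusted over the list alone; median 0.34, camera adjusted p 0.00238, and adjusted p = 0.0903 with an estimated correlation). Dnaja1, Hspb1 and Hsp90ab1 rose by 0.62, 0.53 and 0.31. Endoplasmic reticulum chaperones had 11 of 20 higher and 5 lower (median 0.18, camera adjusted p 0.138), and 10 and 8 with equal totals, with Pdia3 and Dnajc3 up by 1.12 and 0.59 and Sdf2l1 at -0.95.

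Genes of the integrated stress response had 15 of 26 lower and 5 higher (median -0.33, camera adjusted p 0.00315, and adjusted p = 0.302 with an estimated correlation). Chac1 fell by 1.26 and the mitochondrial folate gene Mthfd2 by 0.95, while Atf3 rose by 2.24. Glycolysis and hypoxia genes had 18 of 30 lower and 8 higher (median -0.18, camera adjusted p 0.00357, and adjusted p = 0.201 with an estimated correlation). Pfkp fell from 115 ± 1.32 to 35.2 ± 0.798 on the TPM scale, and Egln3 and Bnip3, targets of hypoxia-inducible factors, fell by 1.55 and 1.22. Cholesterol synthesis genes had 16 of 24 higher and 5 lower (median 0.34, camera adjusted p 0.00487, and adjusted p = 0.214 with an estimated correlation), with Sc5d and Sqle up by 1.27 and 0.72. Cell cycle genes had 19 of 35 higher and 13 lower (median 0.11, camera adjusted p 0.42), which became 11 higher and 14 lower with equal totals (median -0.05). Ccnd1 rose by 1.20 and Top2a, on chromosome 11, fell by 0.63. Imprinted genes had 20 of 38 higher and 10 lower (median 0.38, camera adjusted p 0.0347, and adjusted p = 0.128 with an estimated correlation). Nnat rose from 30.2 ± 1.19 to 310 ± 5.2 and Gnas from 77.7 ± 0.667 to 256 ± 5.35 on the TPM scale, while the noncoding RNA H19 fell from 56.9 ± 1.05 to 8.34 ± 0.388.

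Markers of feeder fibroblasts were higher in the same libraries as the mesoderm and contractile genes, with 26 of 28 higher and 2 lower (median 2.71, camera adjusted p 2.2e-10, and 0.0386 with an estimated correlation). Thbs1 and the growth factor response genes Ccn1 and Ccn2 had the smallest p-values (log2 fold changes 6.0, 3.68 and 2.17). The matrix genes Lox and Col3a1, named after their values were seen, rose by 6.03 and 5.03, to 2.43 ± 0.162 and 3.84 ± 0.284 on the TPM scale (SD, n = 3), and 12 of the 28 genes were already at 1 or more on the TPM scale in WT cells. Replication-dependent histone transcripts, which normally lack a polyA tail, had 30 of 31 lower and none higher (31 lower adjusted over the list alone; median -0.996, camera adjusted p 1.53e-10, and adjusted p = 0.195 with an estimated correlation). Hist1h1a and Hist1h1b fell by 1.27 and 1.19. Small nucleolar RNAs, which also lack a tail, had 88 of 196 lower and 5 higher, with a median of -0.66. These 2 classes are sensitive to how RNA was selected, and their fall coincided with the genotype. Mitochondrially encoded genes had 6 of 15 higher and 4 lower (median 0.03, camera adjusted p 0.616), which became 6 higher and 9 lower with equal totals (median -0.13). The smallest p-values were those of mt-Nd2, mt-Nd1 and mt-Cytb, up by 0.85, 0.75 and 0.60. Y-linked genes had 3 of 8 higher and 3 lower (median -0.17, camera direction up with adjusted p 0.951), with Ddx3y, Eif2s3y and Uty up by 0.64, 0.62 and 0.50. Counts adjusted over the list alone equalled those over all genes in the 23 lists for which none is given.

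Genes on chromosomes 6, 8 and 11 were lower in the knockout as a group, which bears on every gene named from them. The median log2 fold change was -0.29 for 1180 genes of chromosome 6, -0.38 for 1218 genes of chromosome 8 and -0.41 for 1787 genes of chromosome 11 (camera adjusted p 9.26e-05, 1.27e-08 and 2.06e-10, and 0.0108, 0.00139 and 0.0108 with an estimated correlation). Against the other autosomes the medians differed by -0.36, -0.45 and -0.48. Chromosome 18 was higher, with a median of 0.21 over 567 genes (camera adjusted p 0.00465, and 0.0163 with an estimated correlation).

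**Figure D3:**
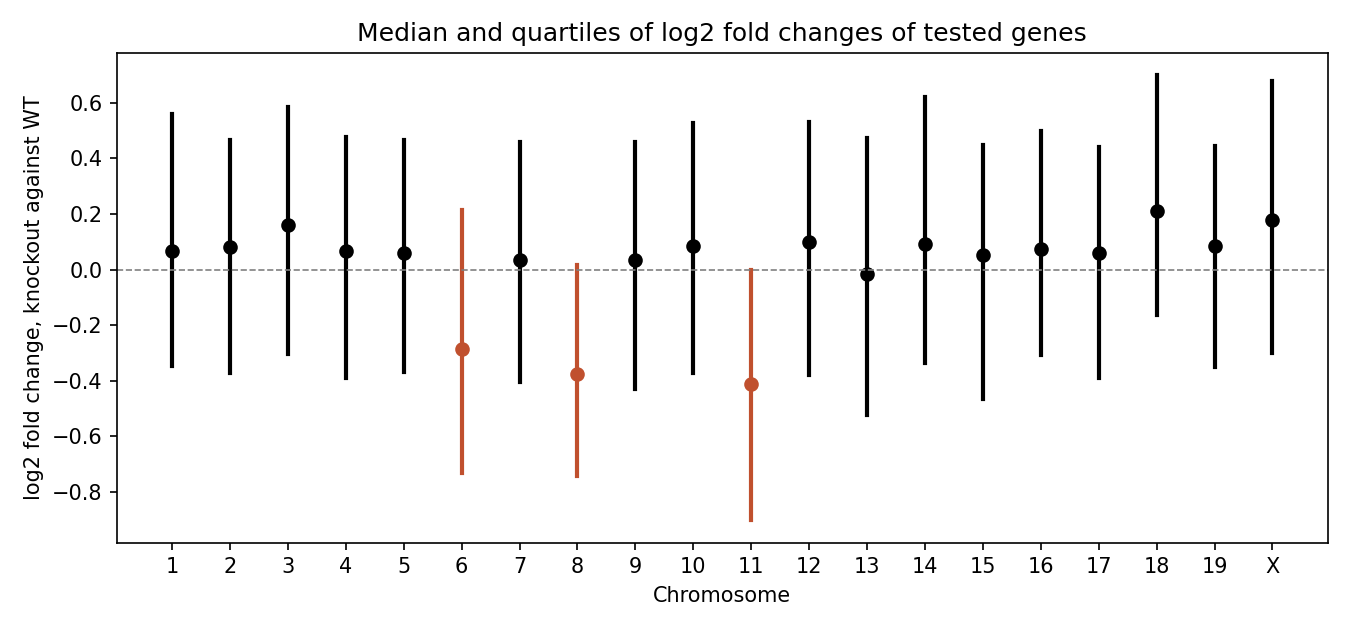
Median (point) and quartiles (line) of the log2 fold change, Mettl5 knockout against WT, of the tested genes of each chromosome. Chromosomes 6, 8 and 11 (red) have medians of -0.29, -0.38 and -0.41, below the medians of the other chromosomes drawn.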

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

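The rescalings to median ratios, upper quartiles and equal totals, the voom weights, the pseudocount of 10 scaled reads, the test against a 1.5-fold change and the chromosome centring were chosen after seeing the data. The fits with edgeR and DESeq2 and the transcript-level test were planned but not run, because the values were neither counts nor per transcript. Mettl5 kept its direction and call in all 18 alternatives (-3.90 to -3.48), and the shifts of chromosomes 6, 8 and 11 kept theirs in all 48 values. Rescaling the libraries moves nearly all genes alike, so the chromosome values under the rescalings were largely fixed in advance. Among 1916 values of other named genes, 1905 kept their side of the threshold, and their direction where they were called. Uncalled genes that changed sign without being called count among these. Nanog went from 0.04 to -0.093 with upper-quartile rescaling, -0.117 with equal totals and -0.132 with totals without the 50 most abundant genes. Trmt112 went from 0.02 to -0.132 with equal totals and -0.148 without the 50 most abundant genes, and Pes1 from -0.40 to 0.016 with chromosome centring. Of 507 list medians under alternatives, 482 stayed on their side of the camera threshold. A call was lost by 24 and gained by 1, ribosome biogenesis with chromosome centring. With at least 10 CPM in 3 samples the call was lost by the formative (adjusted p 0.569), imprinted (0.38), MYC target (0.346), cholesterol (0.167), ribosomal protein (0.167), translation factor (0.119) and heat shock (0.088) lists, and on log2(TPM + 1) by the formative (0.0799), imprinted (0.099), MYC target (0.118) and ribosomal protein (0.146) lists, which also lost it on log2(TPM + 0.1). The other losses were those of the ribosomal protein, translation factor and MYC target lists with upper-quartile rescaling, equal totals and totals without the 50 most abundant genes. Counts of higher and lower genes were 4856 and 3161 with at least 10 CPM in 3 samples, where only 9705 genes were tested, and 2869 and 2178 in the test against a 1.5-fold change, which asks for a larger effect. Changes of at least 1 on the log2 scale numbered 852 higher and 336 lower with that filter, 1026 and 710 on log2(TPM + 1), 1322 and 1147 on log2(TPM + 0.1), and 1485 lower with a pseudocount of 10, which shrinks low genes. Only 14867 genes were tested on the TPM scale, and the cause of the smaller TPM counts was not examined. Of 30 lists, 15 were called higher and 5 lower by camera. The filter left 7 higher, an estimated correlation 7 higher and 1 lower, and fry, which asks another question, called 23 higher. The first principal component held 83.3% on log2(TPM + 0.1) against 97.2%. Other scalings brought the median of all genes from 0.00 down to -0.16 at the lowest, and totals without the 50 most abundant genes gave 6140 higher and 9415 lower. Chromosome centring gave 7927 and 6799. Leaving out 1 library gave 7537 to 7946 higher and 6371 to 6638 lower. With the replicate block, 8183 genes were higher and 6927 lower. Equal replicate numbers are not stated to share a day, and same-numbered libraries deviated together with r of 0.113, 0.079 and 0.132, so no pairing was used. In these deviations, each library correlated best with its own number in the other genotype, a hint from the data only. Small changes can be missed, since 56% of simulated 1.5-fold changes were recovered, and 73.7% of those over 20 scaled reads. Depth was not varied in the simulation, which changed only 200 genes, so these shares need not hold for the real comparison.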

Other observations

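The added gene groups (contractile, keratin, YAP and TEAD, WNT, annexin, S100, interferon, Xlr and metallothionein genes) were chosen after the data were seen, as was the test of the endoderm list against the mesoderm list. Several of the groups were formed from genes with large changes, so counts of their members past the limma threshold are given and no group test. Actin-binding and contractile genes were higher throughout: 18 of 18 tested (median log2 fold change 2.80). Tpm1, a tropomyosin gene, went from 107 to 1089 on the TPM scale, and Cnn1 and Cald1 rose by 4.12 and 3.38. Simple epithelial keratins had 6 of 6 higher (median 4.6), including Krt19 and Krt7 at 3.55 and 4.81. Of 22 genes often used as targets of YAP and TEAD factors, 21 were higher (median 2.08), with Tgfb2, Axl and Amotl2 up by 5.50, 3.57 and 2.52. WNT response genes had 15 of 18 higher and 3 lower (median 1.6), and 15 higher and 0 lower with log2 values centred per chromosome. Wls, the WNT secretion factor gene, went from 1.67 to 73.7 on the TPM scale, and Wnt3 and Wnt4 rose by 5.47 and 4.67. Of the genes in the added groups, Ccn1, Ccn2, Tagln, Acta2, Krt7, Krt8, Krt18, S100a4, S100a6, Wnt3, Wnt8a, Axin2, Cdx1, Cdx2, T, Sp5, Lef1 and Ccnd1 are also in lists fixed earlier, so their values are not new.

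Annexins had 8 of 11 higher and 1 lower (median 0.82), with Anxa1, Anxa3 and Anxa5 up by 4.88, 4.47 and 4.06. S100 genes split, with 6 of 12 higher and 5 lower (median 0.64): S100a11 rose by 2.88 and S100g fell by 4.59. Antigen presentation and interferon genes had 15 of 20 higher and 2 lower (median 0.92). Gbp2b and Gbp2, guanylate-binding protein genes, rose by 4.18 and 4.08 and B2m rose by 1.61, while Bst2 fell by 0.72. All 10 Xlr family genes were lower (median -4.68), but they share reads and are not independent. All 4 metallothionein genes were lower too (median -1.92), and they lie on chromosome 8. Mt3 fell by 3.71 and Mt1 by 0.60. With equal totals the annexins had 2 lower, the YAP and TEAD group 1 lower and the interferon genes 13 higher, and no median of these groups changed sign.

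Genes of chromosomes 6, 8 and 11 were lower along most of their length. Of the 41 windows of 10 Mb with at least 10 tested genes, 97.6% had a median below that of the other autosomes, against 41.5% of 212 windows elsewhere. The exception lay on chromosome 6 (median 0.456). Any lower median counts, and the highest window of chromosome 11 was at 0.028. Single other autosomes had from 0% (chromosome 18) to 76.9% (chromosome 9) of windows below. Weakly expressed genes do not account for it, since genes with a mean of at least 10 on the TPM scale were shifted by -0.455 at the least shifted chromosome, nor do a minority of strongly changed genes, since without genes changed by 1 or more on the log2 scale the smallest of the 3 shifts was -0.286. A difference in copy number between the lines is a candidate explanation, and 2 copies against 3 in every cell would give -0.585. The labels name no separate knockout clones, so a copy number difference acquired in culture would coincide with the genotype, and an effect of Mettl5 loss on these chromosomes stays open as untested.

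Contractile and keratin genes were higher together with feeder fibroblast markers, of which 4 of 28 are in another list. Feeder fibroblasts as their source are argued against by the fibrillar collagens: the summed rise of Col1a2 and Col3a1 was 0.67% of that of Tagln and Acta2, and Col1a1 reached 17.7 on the TPM scale against 732 for Tagln, although S100a6 and Vim, which many cell types express, reached 752 and 294. A lower share of pluripotent cells would lower their genes alike, and 23.5% of the 34 naive and core genes past the threshold rose instead, which lies between the bounds set beforehand and leaves this open. If all other cell types gained share alike, their markers would rise alike. The endoderm list instead had a median of -1.02 (quartiles -1.96 and 0.50), against quartiles of 0.84 and 3.43 for the mesoderm list. That counts only against an even gain, and a gain of some cell types and not others was not tested and stays open. A change of state within the knockout cells may also account for the pattern, and was not tested either.

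Gm14303 was listed at 0 in all 3 WT libraries and at 395, 700 and 842 on the TPM scale in knockout replicates 1, 2 and 3. All of its 31-base words are also in Rps29, which was at 3530 ± 222 in WT and 3935 ± 175 in knockout cells (SD, n = 3), so reads of one could be given to the other. The sum of both genes rose from 3530 ± 222 to 4581 ± 164, which is 162.7% of the Gm14303 change, where 80% or more was set beforehand to count against reads merely moved between the copies at an unchanged total. In all, 2 rules for setting this bound aside were tried after the value was seen: the first, on the change of Rps29 itself, left the question open but did not bear on the bound, and the second asked whether the sum changed as most other ribosomal protein genes did and was not met (log2 ratio 0.38 against an upper quartile of 0.31), so the bound was kept. Moved reads together with a rise of Rps29 are not excluded, since 10 of the 83 other ribosomal protein genes rose by as much as the sum. Rps29 was itself called higher (log2 fold change 0.26, limma adjusted p 0.000467). The bound speaks only to an unchanged total. Because no 31-base word sets Gm14303 apart from Rps29, it does not show that Gm14303 RNA rose.

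With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 15135 genes and was the 1 split of 10 with that many, and the highest of the others called 2.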
